A study of Mus musculus with 2 samples.

How the data were processed

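Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for POU5F1, the POU-domain transcription factor also called OCT4, was carried out in E14TG2a.4, a male mouse embryonic stem cell line. The labels give 1 group with 2 biological replicates, numbered as in the labels. The control experiment named in the labels was not analysed here.

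The authors deposited peak lists on 2 genome builds. On mm10, per the file headers of the accompanying descriptions, a relaxed list of peaks and background was made for each replicate and for both replicates pooled, 300000 entries each, and an irreproducible discovery rate (IDR) procedure, which ranks peaks by how well replicates agree, gave an optimal list of 3994 and a conservative list of 2676 peaks. The lists of the replicates were derived from different numbers of undescribed input files, so their control treatment may not be the same. On mm9, a list was deposited for replicate 1, for replicate 2 and for the whole series. How the replicates were combined in the last is not given in the sources used here, and neither are the aligner, the peak caller and the IDR threshold. The signal of each peak is the value deposited by the authors, whose scaling is not stated, so its levels were not compared between lists. It was used to rank, filter and describe peaks, to compare mean log2 signal between peaks of 1 list, and to correlate the replicates. The deposited mm9 lists give a −log10 p-value per peak, none below 5, and a q-value. The mm10 lists deposited by the authors give −log10 q, which was not used in any test. The score in the deposited IDR lists reaches 1000. No read counts were used, so the depth of each library is unknown, and the number of peaks in a list is not a measure of depth.

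The reference used was NCBIM37 (mm9) with the GENCODE M1 annotation. No mm9 peak lay beyond a chromosome end. Coordinates were never converted between builds. The motif, transcription start site (TSS) and gene list analyses had been designed for the optimal mm10 list, and the plan stated that motif results would not be made if the reference was of another build. No mm10 sequence was used here, so none of these results was made on that list. The mm9 whole-series list of 5515 peaks was used in its place, with the peak centre instead of the summit, and the named-gene rule was applied to it. That replacement was chosen after the data had been seen. The motifs, gene lists, main tests and windows were fixed before the data were examined. Motif shares by peak rank and by presence in the replicate 1 list, and motif distances from the centre, were not part of that design. RefSeq gene bodies on GRCm38, the same assembly as mm10, served for an added gene list test on the mm10 lists.

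Replicates were compared by the share of the 3994 highest-signal peaks of replicate 1 overlapping those of replicate 2 by at least 1 bp, with 1000 shuffles within chromosomes as the null, and by Spearman's rho of signal over optimal peaks. The p-value of the permutation test designed for rho is not given, because the IDR procedure had already selected these peaks. Whether it selected the optimal list on the 2 replicates or on splits of the pooled data is not stated. Of the optimal peaks, 272 overlapped no entry of the relaxed list of replicate 1. This argues against selection of these 272 on the agreement of the 2 replicates, while the other optimal peaks stay undecided. For motifs, a window of 100 bp on each side of the peak centre was searched on both strands for 15 fixed motifs. The composite element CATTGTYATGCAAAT was allowed 2 mismatches and the octamer ATGCAAAT 0. In named peaks the composite element was searched over the whole peak and the other motifs in the same windows as above. Each window was compared with its own window shifted by 2 kb, by a two-sided exact McNemar test with Benjamini-Hochberg adjustment over the 15 motifs. Mean log2 signal with and without the composite element was compared by a two-sided permutation test of 100000 resamples. The share of peaks within 1 kb of a TSS was compared, two-sided, with 1000 shuffles within chromosomes that avoided assembly gaps of at least 1000 bp. A gene was near a peak when any of its TSSs lay within 50 kb of a peak centre. The 17 gene lists, with 391 of 393 symbols matched (8 through an older name), were compared with the other of 22225 protein-coding symbols by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. Intervals are 95% Clopper-Pearson intervals, which cover counting error only. P-values across peaks or genes describe these lists and not the spread between cultures, since peaks and genes are not independent replicates.

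Named genes were, for each list, the up to 4 members near a peak whose strongest peak had the highest signal, all such members among the pluripotency regulators, and the genes nearest to the 10 highest-signal peaks, with Pou5f1, Sox2 and Nanog always named. A gene that this rule selects is not reported here. The motif search recovered 400 of 400 exact copies of the composite element planted in 4000 random windows. A search that allows 2 mismatches must find exact copies, so this checks the code and not the sensitivity to sites with mismatches. Without planting, 0 of 15 motifs were called. In simulations over 22225 genes, each gene was set near a peak independently. With at least 72% of the pluripotency regulators near a peak, their observed share, that list was called in 100 of 100 draws. Without enrichment, some list was called in 3 of 100 draws. Real neighbouring genes can share peaks, so that count need not hold for the data, and lists enriched at lower shares were not simulated. Alternatives covered the overlap rule, the number of peaks, window sizes, control windows, mismatches, distance to genes, each replicate's own mm9 list and a stricter −log10 p of 10, the last added after seeing the data. Leaving out replicate 1 meant the 5515 strongest mm9 peaks of replicate 2, and leaving out replicate 2 meant all 1330 of replicate 1. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and samtools 1.23.1.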

Results

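POU5F1 occupancy was measured by ChIP-seq in 2 biological replicates of E14TG2a.4 mouse embryonic stem cells. On mm9, the authors' lists held 1330 peaks for replicate 1, 6324 for replicate 2 and 5515 for the whole series, with median widths of 265, 288 and 367 bp. On mm10, the optimal list held 3994 peaks and the conservative list 2676. The whole-series and IDR lists carry 1 value per peak, with no replicate error, and read depth is unknown.

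The first question was how far the replicates shared peaks. The strongest peak in both replicates on mm10 was the same site, 0.375 kb from the body of Vamp1, a vesicle-associated membrane protein gene, at chromosome 6, 125215061 to 125215367. The site upstream of Pou5f1 itself (chromosome 17, 35503907 to 35504188) ranked 7 in replicate 1 and 9 in replicate 2. The strongest optimal peak near Sox2, the partner of POU5F1 at many sites, ranked 36 and 52, and that near Nanog, a homeobox pluripotency regulator, ranked 86 and 363. Among the 3994 highest-signal peaks of replicate 1, 1713 overlapped those of replicate 2, which is 42.9% (95% interval 41.3 to 44.4%). Shuffled positions gave a mean of 0.175% and a maximum of 0.426% (permutation p = 0.000999, one-sided, the smallest that 1000 shuffles can give). Random draws of as many entries from the relaxed list of replicate 1 gave a mean of 1.15% and a maximum of 1.78%. The share was 70.4% for the top 500 peaks and 12.45% for the top 39940. Of the optimal peaks, 3722 overlapped an entry of the relaxed list of replicate 1 and 3976 one of replicate 2. Each relaxed list holds 300000 entries of peaks and background, so these overlaps alone say little about replication. No chance level is given for them. Within the 3994 highest-signal entries of each replicate, 1993 optimal peaks were found in replicate 1 and 3202 in replicate 2. Of the optimal peaks, 1720 were in both of these top sets and 519 in neither. Over the 3704 optimal peaks that overlapped both relaxed lists, Spearman's rho of signal was 0.505 and Pearson's r on the log2 scale 0.619. The IDR procedure had already selected these peaks, on the replicates or on the pooled data. The peaks are not independent replicates, so both values describe this list only.

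**Figure D1:**
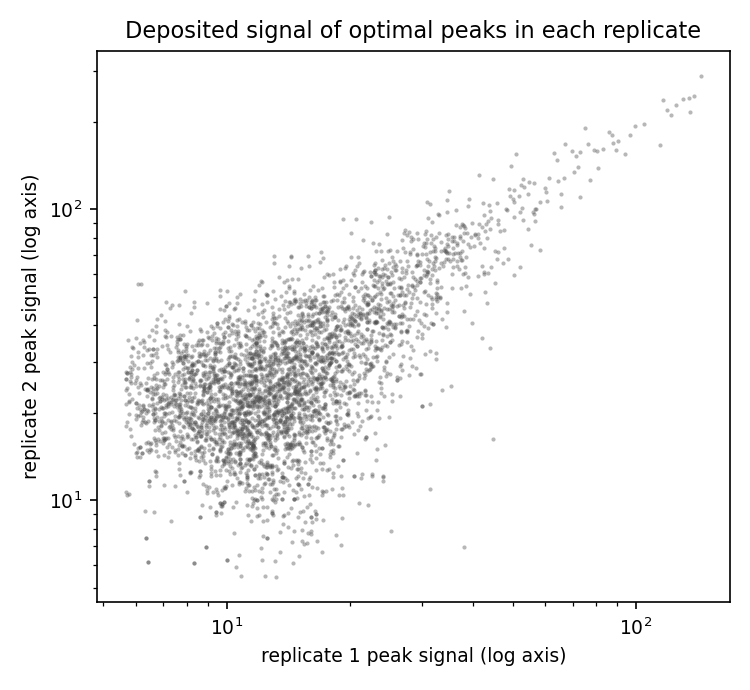
Deposited peak signal in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), each point 1 of the 3704 optimal mm10 peaks found in both relaxed lists. Points rise together, with Spearman's rho 0.505.

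Of the conservative peaks, 2437 overlapped an optimal peak, which is 91.1% (95% interval 89.9 to 92.1%), and 239 overlapped none. On mm9, 1223 of the 1330 peaks of replicate 1 overlapped a peak of replicate 2 (92.0%, 95% interval 90.4 to 93.4%), while 1210 of the 6324 peaks of replicate 2 overlapped a peak of replicate 1 (19.1%). The share of replicate 1 peaks was 66.2% when the replicate 2 list was cut to its 1330 strongest. Of the 5515 whole-series peaks, 1209 were in both replicate lists, 3575 in that of replicate 2 only, 44 in that of replicate 1 only and 687 in neither. Their median signals were 8.63, 5.29, 4.99 and 4.41.

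The next comparison asked which sequence elements lay at the peaks. The composite of a SOX site and a POU octamer was present in 513 of 5515 peak windows, or 9.30% (95% interval 8.55 to 10.1%), and in 4 windows 2 kb away, or 0.0725%. The exact octamer was present in 13.4% of peak windows against 1.40%, and the MORE element, a palindrome bound by POU homodimers, in 2.38% against 0.0907%. The exact McNemar tests gave adjusted p-values of 1.5e-148, 2.2e-142 and 6.1e-33. At least 1 of the composite, octamer, MORE and PORE elements was found in 1211 peaks (22.0%), so 4304 peaks held none under these rules. The shares depended on the mismatches allowed: the composite was present in 1.89% of peak windows against 0% with 1 mismatch, in 28.7% against 1.11% with 3 and in 58.2% against 10.4% with 4, and the octamer with 1 mismatch in 53.7% against 19.9%. The elements lay close to the peak centre, with median distances of 23 bp for the composite and 29 bp for the octamer among matches within 250 bp.

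Other motifs were less enriched. The SOX site, counted with or without a POU element, was present in 11.2% of peak windows against 5.55%, the ZIC site in 9.27% against 5.06%, the TFCP2L1 repeat in 28.7% against 23.1%, the TEAD site in 4.10% against 2.63%, the KLF site in 2.30% against 1.16%, the ESRRB site in 1.38% against 0.562%, the PORE element in 1.76% against 0.653% and the STAT site in 1.02% against 0.526%, all higher in peaks by the exact McNemar test (largest adjusted p = 0.00615). The GATA site was lower in peaks, 1.92% against 2.67% (exact McNemar test, adjusted p = 0.0143). The MYC E-box, CTCF and NFY sites did not pass, with exact adjusted p-values of 0.363, 0.247 and 0.363. With the replicate 1 list alone the calls for STAT, TFCP2L1 and GATA were lost (exact adjusted p = 1, 0.0711 and 0.340), at 0.827% against 0.752%, 28.1% against 24.7% and 1.73% against 2.41% of 1330 windows. The ratio for GATA was then 0.719, against 0.721 over all 5515. With windows of 50 bp on each side the ESRRB call was lost (exact adjusted p = 0.0668). Against windows 2 kb to the other side, the E-box was lower in peaks and the CTCF site higher (exact adjusted p = 0.00153 and 0.0205). The CTCF site was also higher in windows of 250 bp on each side, 6.07% against 4.70% (exact adjusted p = 0.00181), and the NFY site was lower in peaks than in windows matched on GC content, 6.96% against 9.58% (exact adjusted p = 2.0e-06).

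**Figure D2:**
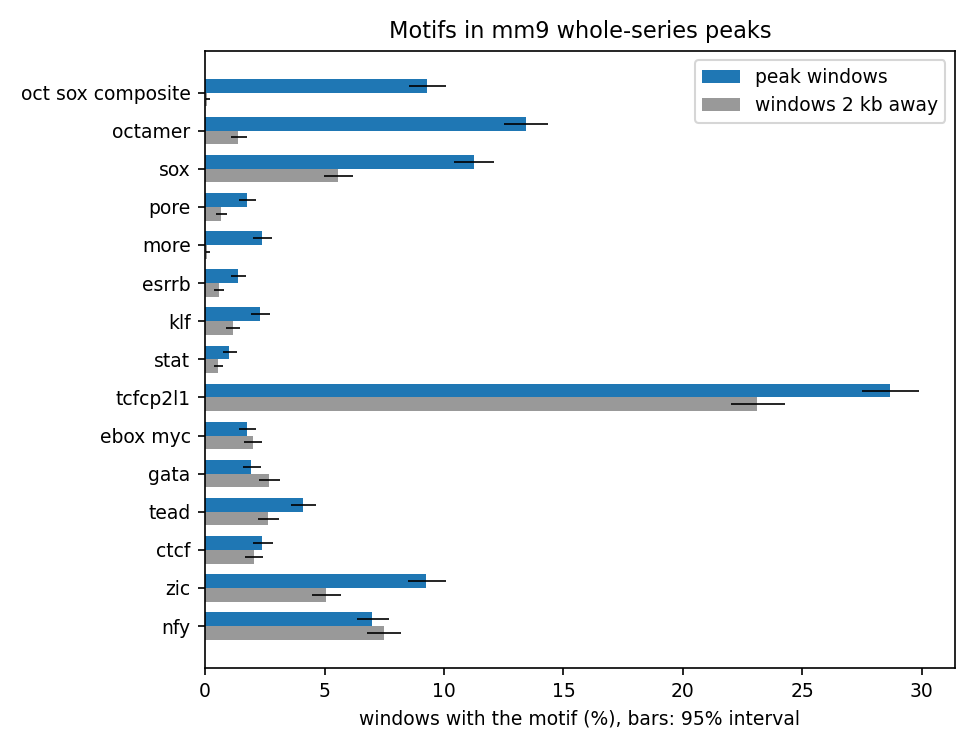
Share of mm9 whole-series peak windows (blue) and of windows 2 kb away (grey) with each of the 15 motifs, in percent, with 95% Clopper-Pearson intervals. The composite element stands at 9.30% against 0.0725% and the octamer at 13.4% against 1.40%.

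Peaks with the composite element had the higher signal. Their mean log2 signal was 2.72 ± 0.53 (SD, 513 peaks) against 2.54 ± 0.46 in the 5002 others, a difference of 0.18 with a standard error of 0.02 (permutation p = 1e-05, the smallest the resamples can give). For the exact octamer the difference was 0.05 (permutation p = 0.0114), with a median signal of 5.58 in both sets. The element was present in 14.8% of the 1103 peaks with the highest deposited −log10 p and in 5.44% of the 1103 with the lowest, while the octamer was present in 14.4% and 11.4%. Whole-series peaks shared with the replicate 1 list held the composite element in 14.05% of cases and the others in 7.91% (Fisher's exact test, adjusted p = 1.2e-09). The MORE element, at 3.59% and 2.02%, and the SOX site, at 14.3% and 10.3%, were also more frequent in the shared peaks (Fisher's exact test, adjusted p = 0.00279 and 0.000324). For the octamer these shares were 13.7% and 13.3% (Fisher's exact test, adjusted p = 0.706).

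**Figure D3:**
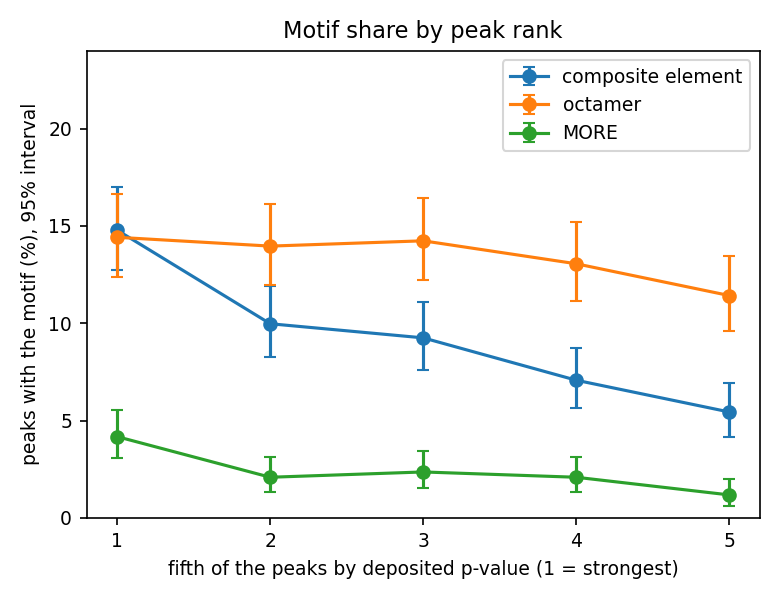
Percent of mm9 whole-series peaks with the composite element, the octamer and the MORE element in each of 5 equal parts of the list ordered by the deposited p-value, 1 being the strongest, with 95% Clopper-Pearson intervals. The composite element falls from 14.8% to 5.44%.

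Most peaks lay away from promoters. Of the 5515 peaks, 581 were within 1 kb of a TSS, or 10.5% (95% interval 9.74 to 11.4%), against a mean of 4.27% for shuffled positions (permutation p = 0.002, two-sided, the smallest that the shuffles can give). A further 34.8% lay in introns and 52.6% between genes, where shuffled positions gave 36.4% and 56.8%. The median distance to the nearest protein-coding TSS was 23.0 kb.

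Genes known for pluripotency were often near a peak. Of the 25 pluripotency regulators, 18 had a peak within 50 kb of a TSS (72%, 95% interval 50.6 to 87.9%), against 27.2% of other protein-coding genes (Fisher's exact test, adjusted p = 2.3e-05). On mm9 the strongest was a peak of signal 27.9 located 1989 bp upstream of Pou5f1, between genes (chromosome 17, 35640669 to 35641316), with signals of 20.53 and 55.17 in the lists of replicates 1 and 2. Next came the promoter of Rif1, a telomere and replication timing factor, at 22.91, a peak 3909 bp downstream of the Sox2 TSS, beyond the end of Sox2 and in an intron of an overlapping annotated transcript (chromosome 3, 34552709 to 34553225) at 19.09, and peaks near Sall1 at 14.49, 1662 bp downstream of the Trp53 TSS in an intron at 9.98 and at the Nanog promoter (chromosome 6, 122657046 to 122657684) at 9.96. The Nanog peak held the composite match CATTGTAATGCAAAA at 122657431 to 122657445 on the minus strand and the Sox2 peak the match CATTGTGATGCATAT at 34552971 to 34552985 on the plus strand, each with 2 mismatches. No match with up to 2 mismatches lay in the Pou5f1 peak. The strongest peaks of Etv5 (9.47), Klf2 (8.81), Zscan10 (8.22), Esrrb (7.93), Tcfcp2l1 (7.34), Klf5 (6.17), Tbx3 (6.17), Nr0b1 (5.91), Mycn (5.58), Sall4 (4.99), Prdm14 (4.82) and Nr5a2 (4.70) were weaker. Of these 12, the peaks of Etv5, Esrrb and Tcfcp2l1 overlapped a peak of the mm9 replicate 1 list. On mm10, Nr0b1, Prdm14 and Nr5a2 had 0 optimal peaks within 50 kb of the gene. The strongest optimal peaks of Klf2, Zscan10, Tbx3, Mycn, Klf5 and Sall4 ranked 319, 632, 1285, 3030, 4207 and 4714 in the relaxed replicate 1 list. In that of replicate 2 they ranked 1559, 1001, 3922, 1915, 1491 and 50385. Coordinates were not converted, so these mm10 peaks need not be the sites of the mm9 peaks above.

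Of 30 genes enriched in embryonic stem cells, 23 were near a peak (76.7%, against 27.2% of other genes, exact adjusted p = 4.3e-07). With the replicate 1 list alone the share was 46.7% against 8.11%, and that of Hox genes 37.5% against 8.13% and of Polycomb genes 35% against 8.13% (exact adjusted p = 1.9e-07, 0.000375 and 0.00303). A peak of signal 19.38 lay 1135 bp upstream of Lefty1, an inhibitor of Nodal signalling, and within 50 kb of Lefty2. Jam2 (14.1) and Utf1 (13.8) followed. Among lists of later lineages, 14 of 23 neuroectoderm genes were near a peak (60.9%, exact adjusted p = 0.00317), led by Zic1 (9.98), Six3 (8.52), Nkx2-2 (7.34) and Hes5 (7.05). With the replicate 1 list alone the neuroectoderm share was 21.7% against 8.14% of other genes and did not pass (exact adjusted p = 0.0744). It also did not pass with peaks of −log10 p of at least 10, at 34.8% against 16.5% (exact adjusted p = 0.0650). Of the 24 Hox genes, 19 were near a peak (79.2%, exact adjusted p = 1.5e-06), but these shared 8 distinct peaks, and counted by nearest TSS the share was 20.8% (adjusted p = 0.596). The peak at the Hoxb1 promoter, of signal 7.34, was also the strongest for Hoxb2 and Hoxb4. For Hoxc10 it was 7.05.

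The Polycomb, DNA methylation and LIF pathway lists also passed at 50 kb. Polycomb genes were near a peak in 11 of 20 cases (exact adjusted p = 0.0277), with Jarid2 at 16.44, Mtf2 at 14.68, Bmi1 at 10.57 and Eed at 7.76. In the DNA methylation list, 9 of 15 genes were near a peak (exact adjusted p = 0.0267). They were led by Ehmt1 at 17.03, Tet2 at 8.14, Dnmt3l at 7.97 and Dnmt3b at 7.05. This list is not limited to DNA methylation enzymes, and Dnmt3l, Trim28 and Zfp57 were also counted among the embryonic stem cell genes. Genes of the LIF and JAK-STAT pathway were near a peak in 9 of 16 cases (exact adjusted p = 0.0479). Il6st at 13.22, Socs2 at 8.81, Pim1 at 8.22 and Lifr at 7.81 led these. The DNA methylation call was lost within 10 kb and 100 kb, by nearest TSS, with the replicate 1 list alone and on both mm10 lists (exact adjusted p = 0.0522 to 0.0883). Its share was 60% against 27.3% of other genes at 50 kb, 26.7% against 8.64% within 10 kb, 26.7% against 8.15% with the replicate 1 list and 40% against 17.5% by nearest TSS. The LIF call was lost within 10 kb and 100 kb, with the replicate 1 list alone and against lists matched on gene density (adjusted p = 0.0573 to 0.194, by exact or permutation test), with 56.25% against 27.3% at 50 kb, 25% against 8.65% within 10 kb and 18.75% against 8.15% with the replicate 1 list.

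The other 10 lists did not pass. Near a peak were 8 of 15 primed epiblast genes (exact adjusted p = 0.068), with Fgf15 at 9.1, Zic2 at 8.22, Dnmt3b at 7.05 and Wnt8a at 6.75, and 10 of 20 FGF and ERK genes (exact adjusted p = 0.068), with Egr1 at 11.45, Etv5 at 9.47, Spred1 at 9.4 and Fgf4 at 9.1. A single peak lay nearest to Fgf15 and also within 50 kb of Fgf4. Ribosomal and housekeeping genes had 17 of 38 (exact adjusted p = 0.0567), with the Vamp1 peak counted for Gapdh, Rpl7 at 11.16, Rps19 at 8.59 and Rpl3 at 7.93. Wnt pathway genes had 9 of 20 (exact adjusted p = 0.127), with Tcf7 at 10.87, Tcf7l1 at 9.4, Wnt8a at 6.75 and Cdx1 at 6.46. Nodal, TGF-beta and BMP genes had 9 of 21 (exact adjusted p = 0.196), with Skil at 18.21 and Id3 at 11.16 after Lefty1 and Lefty2.

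Genes of other lineages were near a peak in shares that did not differ by test from those of other genes. Trophectoderm genes had 7 of 20 (exact adjusted p = 0.594), with Gata2 at 9.4, Tcfap2a at 7.64, Gcm1 at 7.05 and Fgfr2 at 5.87. Mesoderm and primitive streak genes had 7 of 23 (exact adjusted p = 0.907), with Myf5 at 10.57, Mesp1 and Mesp2 at a shared 6.75 and Pax7 at 5.58. Endoderm genes had 6 of 22 (exact adjusted p = 1), with Hhex at 11.75, Gata4 at 6.17, Pdx1 at 5.29 and Foxa1 at 4.99. Feeder fibroblast genes had 4 of 20 (exact adjusted p = 0.751), with Loxl1 at 9.48, Pdgfrb at 6.46, Col3a1 at 5.87 and Fn1 at 5.87. The Pdgfrb peak is the one counted for Cdx1, to which it lay nearest, and the Loxl1 peak lay nearest to Stoml1. A peak counted for a list member was thus not always nearest to it. Genes of terminal somatic cells had 9 of 37 (exact adjusted p = 0.907), with Slc4a1 at 8.52, Cd4 at 7.34 and Ms4a1 at 6.46. By nearest TSS the somatic share was lower than that of other genes, at 2.70% against 17.5% (exact adjusted p = 0.0252). Lists that passed in some other settings were the primed epiblast, FGF, Wnt and Nodal lists, with exact adjusted p-values by nearest TSS of 0.00366, 0.00212, 0.000915 and 0.0110, and the ribosomal list within 10 kb and on the mm10 optimal list (exact adjusted p = 0.0274 and 0.0156). With the replicate 1 list alone the Nodal list passed (exact adjusted p = 0.0185). The primed epiblast list passed with the replicate 2 list alone (exact adjusted p = 0.0205). In the replicate 1 list its share was 20% against 8.15% of other genes, and the Wnt share was 10% against 8.16%.

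**Figure D4:**
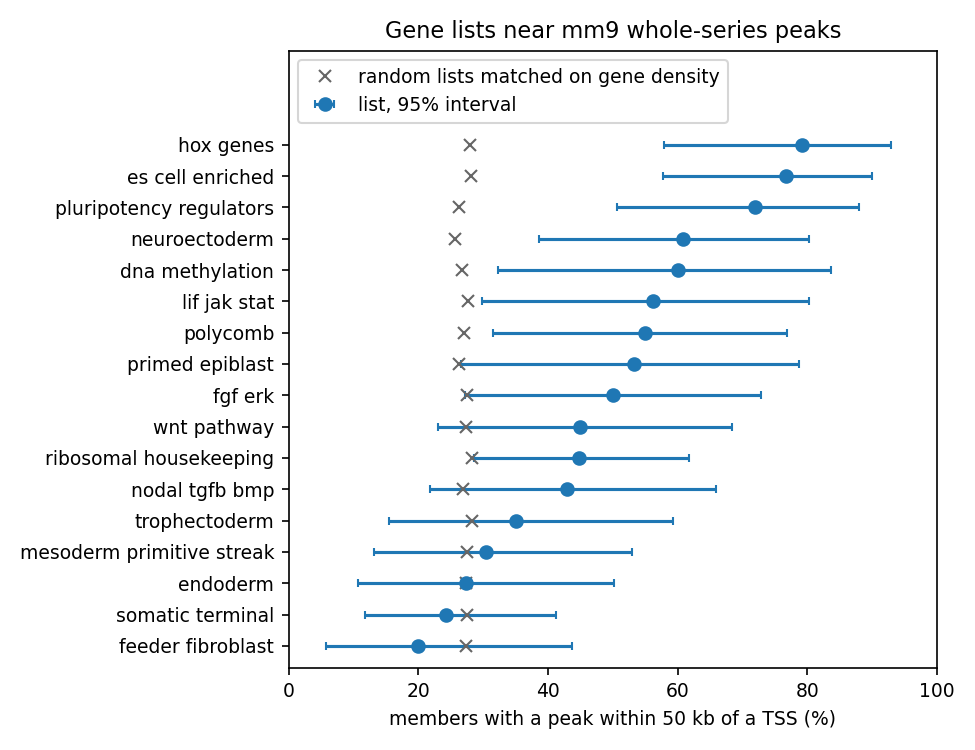
Percent of the members of each gene list with an mm9 whole-series peak within 50 kb of a TSS (points, with 95% Clopper-Pearson intervals) and the mean of random lists matched on gene density (crosses). Genes enriched in embryonic stem cells stand at 76.7% and feeder fibroblast genes at 20.0%.

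The 10 highest-signal peaks on mm9 were nearest to Vamp1 (32.6), Lmtk2 (29.07), Diap3 (28.49), Pou5f1 (27.9), Grp (27.6), Rnf169 (27.31), Prr5 (26.72), Gprc5b (26.14), 2810432D09Rik (25.55) and Iqgap1 (25.26), and each overlapped a peak in both replicate lists. Nearest did not always mean close: the TSS lay 696.9 kb away for Diap3, 56.7 kb for Iqgap1 and 47.4 kb for Prr5. It lay 19.9 kb away for Grp, 16.7 kb for Lmtk2 and 6.28 kb for 2810432D09Rik. For Gprc5b, Pou5f1 and Rnf169 the distances were 2.56, 1.99 and 0.124 kb. The Vamp1 peak lay in the promoter, 295 bp upstream of the TSS (chromosome 6, 125164950 to 125165598), and held a MORE element and no composite match. The Lmtk2, Grp and Prr5 peaks also held a MORE element. A composite match was present in the Diap3 and Prr5 peaks, the latter being GATTGTCATGCAAAT at chromosome 15, 84452654 to 84452668, on the minus strand with 1 mismatch.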

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

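The alternatives with −log10 p of at least 10, 3 mismatches, RefSeq gene bodies and main chromosomes were chosen after seeing the data. The share of top replicate 1 peaks found in replicate 2 was 40.4% with reciprocal overlap of 50%, 40.8% with summits within 100 bp, and 56.3%, 28.6% and 12.45% with 1997, 7988 and 39940 peaks. The share of conservative peaks in the optimal list was 89.9% with identical coordinates. The share of mm9 replicate 1 peaks in replicate 2 was 76.6% with reciprocal overlap and 66.2% with lists of equal length. For these the cause was not tested beyond the stricter rule or the changed number of peaks. The rank correlation ranged from 0.423 to 0.583 over its alternatives. The composite, octamer, signal and TSS results kept their direction and side of the threshold in every alternative run. With 1 replicate list at a time, the composite share was 9.16 to 13.6%, the octamer share 13.5 to 13.6%, the signal difference 0.13 to 0.20, the TSS share 10.5 to 11.2% and the number of lists 5 to 8. The number of lists that passed was 5 to 10 over all alternatives. Directions turned only for results that did not pass in the main analysis, and none passed after turning: E-box 5.78% (250 bp), NFY 7.29% and endoderm 9.09% (replicate 1 list alone; 6.85% and 22.7% with that of replicate 2 kept the direction), mesoderm 26.1% and somatic 27.03% (replicate 2 list alone; 8.70% and 5.41% with that of replicate 1 kept it), mesoderm 39.1% and trophectoderm 40% (100 kb), endoderm 31.8% (nearest TSS), feeder 20% and somatic 21.6% (−log10 p of at least 10), somatic 27.03% and endoderm 18.2% (mm10 optimal and conservative); the cause was not tested. The conservative list was not run for motifs, signal by motif, TSS share and genes within 50 kb of a TSS, since no mm10 sequence or TSS annotation was used here. Among single motifs and gene lists, 190 values in other settings kept direction and call, 25 gained a call and 17 lost it. No paired analysis was possible because there is 1 group. Unknown depth limits any statement on absent peaks.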

Other observations

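The tests of non-specific peaks and of shoulder peaks were chosen after related values had been seen, and the 8-mer, promoter and chromosome values and those for peaks without a POU element were not planned. Neither were the motif shares by peak rank and by presence in the replicate 1 list, or the motif distances, given above. Without any motif given, the 8-mer with the smallest p-value for peak windows against windows 2 kb away was the octamer ATGCAAAT (740 against 77 windows), followed by TATGCAAA (614 against 43) and CATAACAA (528 against 39), whose reverse complement TTGTTATG runs from the SOX part into the POU part of the composite element. The variant octamer ATGCTAAT was found in 429 against 36 windows. A peak without a POU element is one without a match under the rules above. Some such peaks held weaker matches, since the octamer with 1 mismatch was present in 2963 peak windows, against 1211 peaks with any POU element. Among the 4304 peaks without a POU element, the ZIC site remained higher than 2 kb away (9.36% against 4.97%, exact McNemar adjusted p = 1.2e-14), as did the ESRRB site (1.60% against 0.581%, adjusted p = 1.7e-05) and the SOX site (9.20% against 5.86%, adjusted p = 2.2e-08). The KLF, TFCP2L1 and TEAD sites also stayed higher and the GATA site lower (largest exact McNemar adjusted p = 0.0159), while the STAT site no longer passed (0.743% against 0.441%, exact adjusted p = 0.126). The X chromosome had 0.518 whole-series peaks per Mb, 0.228 times the autosomal density. Promoter peaks held the composite element in 7.23% of cases and other peaks in 9.55%, a difference that did not pass (Fisher's exact test, adjusted p = 0.204). Other peaks matched on GC content gave 8.83%.

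Replicate 1 had 1330 mm9 peaks and replicate 2 had 6324. Non-specific extra peaks as the whole cause are argued against by the composite element, present in 7.0% of the 5114 peaks of replicate 2 alone and in 0.137% of windows 2 kb away (exact McNemar p = 3.3e-97), although the 1210 shared peaks held it in 14.96%. Of the 2286 strong replicate 2 peaks on mm10 missing from the top of replicate 1, 69.2% overlapped its relaxed list, against 13.8% of as many peaks from the lower part of the replicate 2 list, which is consistent with the same sites lying below the threshold in replicate 1. Depth, enrichment and the different undescribed inputs of the replicates stay open, and no biological explanation was tested.

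Of the optimal peaks, 131 ranked below 20000 in the pooled list. A stronger optimal peak lay within 500 bp of 118 of them (90.1%) and of 1.16% of the other 3863 (Fisher's exact test, p = 2.6e-172). These low-signal entries may be shoulders of stronger peaks. No biological explanation was tested.

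Between Hrh1 and Atg7 on chromosome 6, the mm9 whole-series list held 36 peaks in 160 kb (114433291 to 114593148), the replicate 1 list 7 and the replicate 2 list 25. The highest whole-series signal there was 6.15. A POU element was present in 0 of the 36 (0%, 95% upper bound 9.74%) against 22.1% of the other peaks (Fisher's exact test, p = 0.000177), so the run may be enrichment that does not follow POU elements. The mm10 optimal list held 0 peaks between the same genes, a density ratio of 0 to the genome-wide 1.52 per Mb. At that density 0 is a common count in 160 kb, so the dense run was absent from this list. Peak calling of the mm9 lists may be a source. The optimal list is filtered, however, so weak enrichment could be absent from it as well, and the count cannot separate these. A copy number gain in this line and the control used stay open, and no biological explanation was tested.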
